A study of Mus musculus with 4 samples.

How the data were processed

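Spleen cells of 4 groups of mice (wild-type or labelled TRIF-KO, injected with PBS or TNF) were profiled with droplet-based single-cell RNA sequencing from 10x Genomics, 1 library per group. Per the labels' protocols, single-cell suspensions were made 4 h after injection, red blood cells were lysed, dead cells were removed with magnetic beads, and libraries were sequenced paired-end on a NextSeq 550. The labels do not say how many mice entered a library. Groups were taken from the genotype and treatment labels of each sample.

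The deposited files hold raw UMI counts, whole numbers per gene and barcode, for 32285 features per library. Per the submitters' processing notes, Cell Ranger 3.0 and Seurat 4.1.1 were used with the mouse build mm10, while the headers of the deposited count matrices name Cell Ranger 6.0.1. The annotation release is not given in the sources used here. The smallest barcode held 503, 500, 500 and 500 UMIs, so barcodes had been selected before deposit, whereas the deposited counts still held barcodes with many mitochondrial UMIs. A UMI count collapses copies made by PCR, so that each counts 1 captured molecule, and the reads come from the 3' or 5' end of a transcript. Coordinates are those of the GENCODE M21 annotation of GRCm38 matched by Ensembl gene ID.

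Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept (2502, 5254, 5659 and 7061), and the highest Scrublet scores (expected rate 0.06) of each library were removed as doublets at 0.8% per 1000 barcodes, which took 54, 288, 295 and 455 barcodes. Kept cells held 22395169, 29941602, 29408091 and 58983224 UMIs. Library pairs shared 3 to 15 barcodes. Cells of all libraries were clustered together on 2000 variable genes without the genes of the response lists and without sex-linked, mitochondrial, ribosomal, haemoglobin, immunoglobulin and T-cell-receptor genes, with each cell scaled to 10000 UMIs, 30 principal components, 15 neighbours and Leiden resolution 1, which gave 27 clusters. No batch correction between libraries was applied. Clusters were called after the best of 28 marker lists, by the mean log2 enrichment of its markers (pseudocount 20 CPM, minimum 0.5, at least 3 markers detected, at least 10 cells, and among the top 10 genes no more markers of another class than of its own). 26 clusters were named and 8 cells, all of the wild-type PBS library, stayed unnamed. The names rest on RNA markers alone and are given as "-like".

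UMIs were summed per library and class and expressed as CPM of the class total. A class was compared where each library had at least 50 of its cells, which held for B-like (1205, 2680, 2838 and 2936 cells), T-like (454, 1076, 1302 and 1365), NK-like (68, 71, 135 and 72), neutrophil-like (166, 82, 99 and 351), monocyte/macrophage-like (132, 171, 224 and 332) and dendritic-like cells (62, 164, 148 and 181). A gene was measured in a class with at least 100 UMIs over the 4 libraries and 50 CPM in at least 1. The ratio between 2 libraries has an exact conditional 95% interval, a CPM value an exact Poisson interval and a share an exact Clopper-Pearson interval. The difference between the responses is the log2 ratio of TNF to PBS in the libraries labelled TRIF-KO minus that in wild-type, with 0.5 added to each count and a normal approximation for its interval. Cells are not replicates, so no p-value was computed, and a count of genes past 2-fold is a count of sizes, set beside the mean count from 20 draws of Poisson noise without any difference. Ratios against 0 UMIs are lower bounds against a floor of 3 counts in that library, and no difference between responses is given for a gene with 0 UMIs in a library. The intervals take no account of UMIs that lie together in 1 cell, and the largest share of 1 cell was counted for the named genes after the values were seen. Genes whose CPM in a class was under 5% of their CPM in another class of the same library, which free RNA in droplets can produce, were left out of the counts and of the naming.

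Genes named in the text were chosen by a rule. Per comparison and class these were the 4 highest and 3 lowest ratios (3 and 3 for the difference between responses), ranked by the interval bound nearest to 1 among measured genes at least 2-fold different, without mitochondrial, ribosomal, immunoglobulin, T-cell-receptor, haemoglobin, sex-linked and predicted genes, together with up to 4 members of each gene list and with Ticam1, Cd14, Ticam2, Tnfrsf1a and Tlr4 in every class. The text gives a part of the list members that the rule allows. 2 results that the rule gave are not reported here. The 15 lists cover NF-kB targets and feedback, chemokines, inflammatory cytokines and effectors, type I interferon-stimulated genes, interferon-gamma-responsive GTPases and antigen processing, cell death machinery, TLR4 and TNF receptor pathway components, neutrophil granule and surface proteins, glucocorticoid-responsive genes, lymphocyte activation and egress, dissociation and heat-shock stress, glycolysis, hypoxia and metal response, cell cycle, haemoglobin and erythroid RNA, and sex-linked transcripts. Some genes stand in more than 1 list, for example Mt1 and Mt2 in the glucocorticoid and the metal list. A list with at least 5 measured members was described by its median, relative to that of all measured genes, and by the percentile of the median among 10000 random lists drawn from 10 expression bins. Groups, marker lists, gene lists, the rule for naming genes and the first set of alternative settings were fixed before the data were examined. The thresholds of the naming score of clusters, the use of relative medians and the division of monocyte-like from macrophage-like cells were chosen afterwards.

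The calculation was tested on simulated counts with 200 genes changed by known folds. For the wild-type response, genes raised or lowered 3-fold were called at least 2-fold different in 100% of cases in B-like, T-like and dendritic-like cells, 98.5% in monocyte/macrophage-like and 92.5% in NK-like and neutrophil-like cells, and the intervals held the true value for 94.3% of genes in B-like cells. The alternative settings were a stricter cell filter (at least 500 genes and at most 5% mitochondrial UMIs), doublets kept, Leiden resolution 2, clustering with the response genes, median-of-ratios scaling, CPM without mitochondrial, ribosomal, haemoglobin and immunoglobulin genes (the abundant gene families), UMIs thinned to the smallest class total, the mean over cells, a low filter of 20 UMIs, free-RNA genes kept, another denominator of shares and, for Ticam1, all barcodes. Added after the data were seen were dendritic-like cells with fewer than 5 UMIs of Ngp, Camp and Ltf together, monocyte/macrophage-like cells without those holding Alox15 or Prg4, named genes without the cell with most UMIs of the gene in each library (the top cell), macrophage-like clusters with cells of all libraries alone, and monocyte-like and macrophage-like cells apart. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.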

Results

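Single-cell RNA sequencing was carried out on spleens of 10-week-old mice 4 h after an intravenous injection of 100 µl PBS or of PBS with 9 µg recombinant mouse TNF, a cytokine that drives acute inflammation. The 4 libraries formed a 2-by-2 design with 1 library per group, namely wild-type C57BL/6 with PBS, wild-type with TNF, and the libraries labelled TRIF-KO with PBS and with TNF. TRIF, encoded by Ticam1, is an adaptor of Toll-like receptors 3 and 4. The series set out to examine how its absence affects the response of spleen cells to TNF. The count tables held 2683, 6855, 6508 and 8060 barcodes with 23614028, 34774147, 33771809 and 67276803 UMIs (unique molecular identifiers, each counting 1 captured RNA molecule). This order, wild-type PBS, wild-type TNF, TRIF-KO PBS and TRIF-KO TNF, is kept throughout. After filtering, 2448, 4966, 5364 and 6606 cells remained, with medians of 6872, 4665.5, 4405 and 7182 UMIs per cell. With 1 library per group no difference could be tested against a spread between mice. The 95% intervals given after values cover counting error only, and each comparison is between libraries.

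The targeted gene Ticam1 (ENSMUSG00000047123, mouse build GRCm38, chromosome 17, 56269319 to 56276786, minus strand) was detected in all 4 libraries and was not lower in those labelled TRIF-KO. It had 154, 113, 248 and 337 UMIs in kept cells, or 6.88 (5.83 to 8.05), 3.77 (3.11 to 4.54), 8.43 (7.42 to 9.55) and 5.71 (5.12 to 6.36) CPM, UMI counts scaled to a total of 1000000. By class it stood at 9.01, 5.41, 12.5 and 9.21 CPM in B-like cells, 3.81, 2.74, 4.18 and 4.08 CPM in T-like cells and 18.6, 5.99, 9.92 and 5.86 CPM in NK-like cells. In myeloid cells Ticam1 stood at 16.5, 12, 14.2 and 16.6 CPM in monocyte/macrophage-like and 10.8, 8.56, 17.7 and 4.82 CPM in dendritic-like cells. Neutrophil-like cells had 4.90, 0, 6.61 and 8.07 CPM, the 0 allowing up to 7.90 CPM. The labels do not name the allele, and a 3' tag outside a deleted part checks nothing. The RNA therefore neither checks nor contradicts the genotype labels, and the libraries are called by their labels throughout.

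The partners of TRIF differed strongly between classes. Cd14, a co-receptor for lipopolysaccharide, was higher with TNF in phagocytes of both genotypes, at 233, 3956, 116 and 1703 CPM in neutrophil-like and 43.1, 1439, 48.1 and 617 CPM in monocyte/macrophage-like cells. After TNF, Cd14 was lower in the library labelled TRIF-KO in both (log2 -1.22, -1.29 to -1.14, and log2 -1.22, -1.34 to -1.10, in this order). In neutrophil-like cells it was lower with PBS too, so no smaller response is shown. In the other 4 classes Cd14 was read at up to 7.49 CPM, with upper limits of up to 15.4 CPM. Tnfrsf1a, which encodes TNF receptor 1, was read at 311, 133, 244 and 202 CPM in neutrophil-like, 162, 116, 143 and 137 CPM in monocyte/macrophage-like and 48.3, 19.3, 52.2 and 17.2 CPM in dendritic-like cells. It stood at 32.5, 15, 39.7 and 21.5 CPM in NK-like and 17.9, 11.1, 19.8 and 14.3 CPM in T-like cells, against 0.468, 0.314, 0.159 and 0.304 CPM in B-like cells. Ticam2, which encodes the TLR4 adaptor TRAM, was read mainly in monocyte/macrophage-like cells (35.3, 13.4, 37.9 and 31.6 CPM) and dendritic-like cells (15.8, 17.1, 20.7 and 22.0 CPM). In the other 4 classes it was read at up to 2.81 CPM, with upper limits of up to 12.2 CPM. Tlr4 stood at 116, 60.0, 46.2 and 46.4 CPM in neutrophil-like, 18.0, 6.68, 22.1 and 16.6 CPM in monocyte/macrophage-like and 9.60, 5.02, 7.61 and 7.34 CPM in B-like cells. In T-like, NK-like and dendritic-like cells it had at most 4 UMIs per library, up to 12 CPM (3.26 to 30.7) in the few NK-like cells of wild-type with TNF.

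The first comparison asked which cell classes were recovered after TNF. Neutrophil-like cells made up 6.78% (5.82 to 7.85) of the kept cells with PBS and 1.65% (1.32 to 2.05) with TNF in wild-type. In the libraries labelled TRIF-KO they made up 1.85% (1.5 to 2.24) and 5.31% (4.78 to 5.88). The ratios of TNF to PBS were 0.244 (0.188 to 0.316) and 2.88 (2.31 to 3.59). Monocyte-like cells were a smaller share with TNF in both genotypes (3.27 and 1.11%, then 2.09 and 1.32%). Macrophage-like cells stood at 2.12 and 2.34% in wild-type and at 2.09 and 3.71% in the libraries labelled TRIF-KO. NK-like cells were a smaller share with TNF in both, with ratios of 0.515 (0.370 to 0.715) and 0.433 (0.326 to 0.575). B-like cells (49.2, 54.0, 52.9 and 44.4%) and T-like cells (18.5, 21.7, 24.3 and 20.7%) had ratios above 1 in wild-type and below 1 in the libraries labelled TRIF-KO. Dendritic-like cells made up 2.53, 3.30, 2.76 and 2.74% and erythroid-like cells 10.3, 10.6, 7.08 and 16.9%. Plasma-cell-like, progenitor-like and platelet-like cells made up 0.141 to 2.24%.

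Intervals of the shares are exact binomial intervals. Neutrophil-like and monocyte-like cells lay in different clusters with PBS and with TNF, whereas both dendritic-like clusters held cells of all 4 libraries. Macrophage-like cells lay in cluster 17 (49, 116, 100 and 245 cells) and, with PBS only, also in cluster 13 (3, 0, 12 and 0 cells), which held 32.8% of their UMIs in wild-type and 45.2% in the PBS library labelled TRIF-KO. Neutrophil-like cells of the PBS libraries lay mostly in cluster 11 (161, 0, 95 and 0 cells) and those of the TNF libraries in cluster 25 (5, 82, 4 and 351 cells). Monocyte-like cells likewise lay in clusters 14 (80, 0, 112 and 0 cells) and 26 (0, 55, 0 and 87 cells). Red-cell lysis and dead-cell removal before loading, and a mitochondrial filter that 6.26, 22.4, 10.8 and 11.6% of barcodes exceeded, can set such shares.

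**Figure D1:**
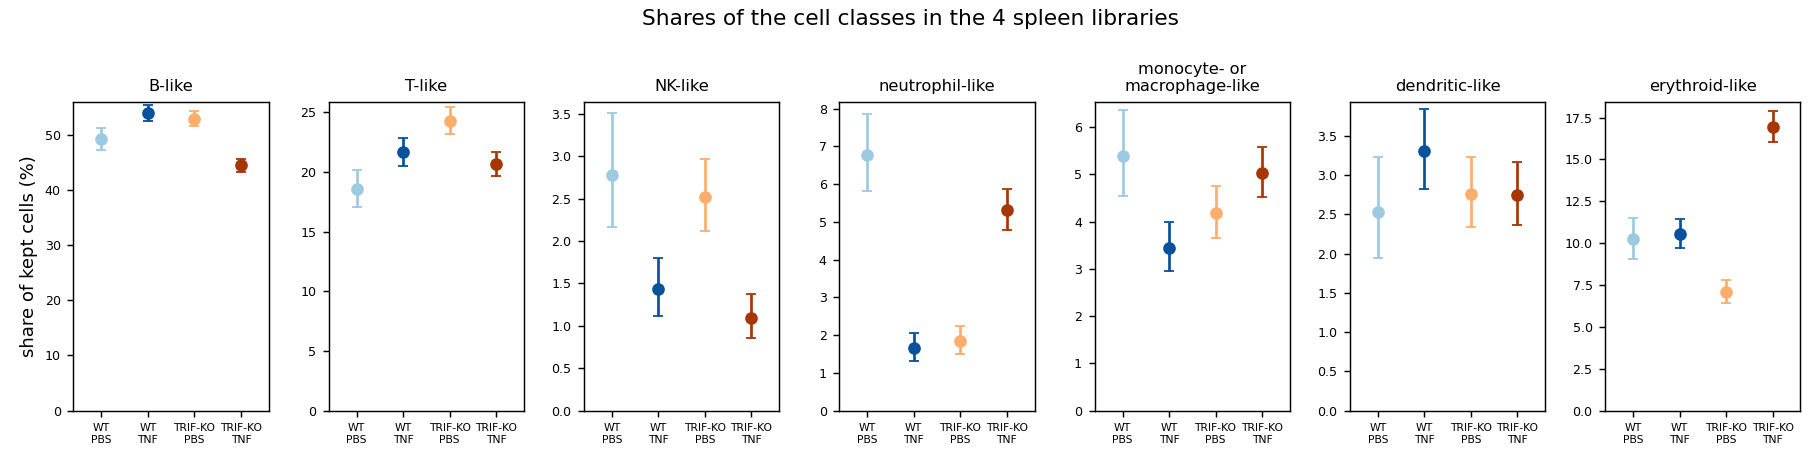
Share of kept cells (%, vertical axis from 0, a scale per panel) of 7 cell classes in the 4 libraries, with points for the shares and bars for exact 95% binomial intervals that cover counting error only. Neutrophil-like cells stood at 6.78% and 1.65% in the wild-type libraries and at 1.85% and 5.31% in those labelled TRIF-KO.

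The next comparison, TNF against PBS in wild-type mice, asked what TNF did to RNA levels within each class. Monocyte/macrophage-like cells showed 428 genes at least 2-fold higher and 783 lower among 3953 measured, neutrophil-like cells 322 and 800 of 2990 and dendritic-like cells 271 and 543 of 3454. NK-like cells showed 112 and 291 of 2802, T-like cells 91 and 129 of 2758, and B-like cells 39 and 59 of 3008. Counting noise alone gave at most 8.6 genes higher and 14.8 lower in a class. The median of all measured genes lay at log2 -0.21, -0.37, -0.20, -0.15, -0.14 and -0.14 in the same order of classes. Median-of-ratios scaling, which moves that median to about 0, gave 559 higher and 576 lower, 478 and 484, 336 and 412, 153 and 188, 113 and 86, and 54 and 39. CPM without mitochondrial, ribosomal, haemoglobin and immunoglobulin genes gave 135 and 211 in NK-like, 108 and 94 in T-like and 50 and 41 in B-like cells. For this reason the medians of gene lists below are log2 values relative to the median of all measured genes of the class. This choice was made after the values were seen. Each median is followed by its percentile among 10000 random lists of matched expression, as a description of these libraries. Where list members had 0 UMIs in a library, the median with these genes at the 3-count floor is given as well. Of 251 named values at least 2-fold, 13 were no longer so in the same direction without the top cell, the cell with most UMIs of the gene in each library.

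In wild-type monocyte/macrophage-like cells the largest ratios were those of the neutrophil chemoattractant Cxcl2 (0.783 and 632 CPM, log2 9.66, 7.17 to 14.96) and the membrane metalloproteinase Mmp14 (1.57 and 477 CPM, log2 8.25, 6.39 to 11.30). Next were the cystine transporter Slc7a11 (3.92 and 645 CPM, log2 7.36, 6.13 to 8.99) and AA467197 (at least 314-fold higher, 0 and 552 UMIs). The serum amyloid gene Saa3 (log2 4.91, 4.60 to 5.23) and the interleukin 1 receptor antagonist Il1rn (log2 5.67, 5.07 to 6.34) were among the inflammatory effectors that were higher. The formyl peptide receptor Fpr2 (log2 4.69, 4.20 to 5.23) and Acod1 (at least 73.3-fold higher, 0 and 129 UMIs), the enzyme that makes itaconate, were others. The lowest ratios were those of the monocyte chemokine receptor Ccr2 (1559.8 and 98.9 CPM, log2 -3.98, -4.33 to -3.64), a marker used to name the class, and of the collagenase Mmp8 (417 and 16.0 CPM, log2 -4.70, -5.66 to -3.88). Mtus1 (129 and 2.67 CPM, log2 -5.60, -8.65 to -3.72) was also among the lowest. NF-kB target and feedback genes were higher as a group (22 of 30 at least 2-fold higher, 0 lower, median 1.89, percentile 100). Among them were the survival gene Bcl2a1b (log2 5.79, 5.41 to 6.20), Sod2 (log2 4.62, 4.38 to 4.88), a mitochondrial superoxide dismutase, and Ehd1 (log2 4.58, 4.20 to 4.98). Inflammatory cytokines and effectors (12 of 15 at least 2-fold higher, 0 lower, median 2.70, percentile 100) and chemokines (4 of 7 at least 2-fold higher, 1 lower, median 2.32, percentile 99.99) were also higher. Of the chemokines, Cxcl16 (log2 5.05, 3.97 to 6.39) was higher and Ccl6 (log2 -2.71, -3.05 to -2.38) lower. With each cell weighted equally Cxcl16, Bcl2a1b, Ehd1, Fpr2 and AA467197 stood at log2 3.18, 4.29, 3.20, 3.599 and 7.03, and with the stricter filter Cxcl16 stood at log2 6.67.

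In wild-type neutrophil-like cells the excess of lower genes depended on scaling. Bcl2a1b (2 and 274 UMIs, log2 7.90, 6.04 to 10.96), Sod2 (14.7 and 1693 CPM, log2 6.85, 6.03 to 7.81), Saa3 (at least 167-fold higher, 0 and 286 UMIs) and the kinase gene Ikbke (at least 75.8-fold higher, 0 and 130 UMIs) had the highest ratios. Dck (339 and 15 CPM, log2 -4.50, -5.83 to -3.44), Prr5l (161 and 2 UMIs, log2 -5.52, -8.58 to -3.65) and the DNA repair gene Xpc (at least 18.5-fold lower, 97 and 0 UMIs) had the lowest. The NF-kB list had 18 of 28 at least 2-fold higher, 0 lower, median 2.06, percentile 100. Its members included Icam1 (log2 6.33, 4.95 to 8.22), an adhesion molecule, and Traf1 (1 and 156 UMIs, log2 8.09, 5.59 to 13.40). With UMIs thinned to the smallest class total Traf1, Saa3 and Ikbke stood at log2 5.21, 6.01 and 4.87. Chemokines were higher (5 of 6 at least 2-fold higher, 1 lower, median 4.30, percentile 100). Examples were Cxcl2 (log2 4.18, 4.01 to 4.36), Ccl3 (log2 3.66, 2.65 to 4.85) and Cxcl3 (at least 64.7-fold higher, 0 and 111 UMIs). Type I interferon-stimulated genes were lower (0 of 27 at least 2-fold higher, 16 lower, median -0.68, percentile 0.26), for example Rsad2 (log2 -3.03, -4.01 to -2.18) and Slfn5 (log2 -3.40, -4.33 to -2.60). Granule and surface proteins went both ways (9 of 27 at least 2-fold higher, 6 lower, median 0.51, percentile 99.0). The granule genes Camp (log2 2.06, 1.99 to 2.14) and Ngp (log2 1.86, 1.80 to 1.93) were higher and the G-CSF receptor Csf3r (log2 -1.88, -2.05 to -1.72), a naming marker, was lower. With each cell weighted equally Camp and Ngp stood at log2 3.44 and 3.20, and 6 cells held the 2009 UMIs of Camp with PBS.

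In wild-type dendritic-like cells the fatty-acid-binding protein Fabp5 (55.2 and 5036 CPM, log2 6.51, 6.13 to 6.92), the actin bundler Fscn1 (5.91 and 563 CPM, log2 6.57, 5.44 to 8.03), the chemokine Ccl17 (at least 37.6-fold higher, 0 and 104 UMIs) and the metallothionein Mt2 (at least 35.5-fold higher, 0 and 98 UMIs) had the highest ratios. The lymph-node homing receptor Ccr7 (log2 4.62, 4.15 to 5.13) and Gadd45b (log2 3.58, 3.08 to 4.12) were also higher. NF-kB genes (17 of 25 at least 2-fold higher, 0 lower, median 1.79, percentile 100) and chemokines (4 of 6 at least 2-fold higher, 0 lower, median 2.90, percentile 100) were higher as groups. Lymphocyte activation and egress genes were higher as well (7 of 13 at least 2-fold higher, 3 lower, median 1.33, percentile 100). The lowest ratios were those of the neutrophil granule genes Ngp (846 and 3 UMIs, log2 -8.02, -10.30 to -6.47), Camp (377 and 2 UMIs, log2 -7.44, -10.49 to -5.58) and Ltf (316 and 1 UMIs, log2 -8.19, -13.49 to -5.70). The granule list as a whole had 0 of 14 at least 2-fold higher, 11 lower, median -5.07, percentile 0. These genes are known from another cell type, and 1 cell of the wild-type PBS library held 844 of the UMIs of Ngp, 377 of Camp and 316 of Ltf. Without the top cell the value of Ngp turned to log2 0.067, and without cells holding these genes the granule list stood at -0.26. Fscn1 had 6 UMIs in the 62 cells of that library, against 192 in the PBS library labelled TRIF-KO.

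With TNF, wild-type T-like and NK-like cells shared higher RNA of NF-kB genes. The list had 9 of 17 at least 2-fold higher, 0 lower, median 1.35, percentile 100 in T-like and 9 of 15 at least 2-fold higher, 0 lower, median 1.45, percentile 100 in NK-like cells. In T-like cells the highest ratios were those of Frmd4b (1.57 and 57.6 CPM, log2 5.20, 4.14 to 6.52), Gadd45g (3.58 and 71.7 CPM, log2 4.32, 3.61 to 5.14) and the cytotoxic protease granzyme B, Gzmb (6.94 and 77.7 CPM, log2 3.48, 2.96 to 4.06). With PBS 27 of the 31 UMIs of Gzmb lay in 1 cell (log2 6.36 without the top cell). The OX40 receptor followed, Tnfrsf4 (15.5 and 121 CPM, log2 2.96, 2.61 to 3.34). The lowest ratios in T-like cells were those of Id3 (log2 -3.26, -3.71 to -2.83), the heat-shock gene Hsph1 (log2 -2.93, -3.33 to -2.55) and the chemokine Xcl1 (log2 -2.43, -2.82 to -2.05). In NK-like cells the highest were those of Cxcl10 (at least 49.8-fold higher, 0 and 116 UMIs), Serpina3f (log2 4.61, 3.20 to 6.53), Serpina3g (log2 3.14, 2.77 to 3.53) and the cold-inducible RNA-binding protein Rbm3 (log2 2.96, 2.51 to 3.44). The chemokine Ccl4 (log2 -2.78, -3.36 to -2.25), Tm6sf1 (log2 -2.92, -3.68 to -2.23) and the transcription factor Zeb2 (log2 -2.65, -3.20 to -2.14) had the lowest. Interferon-gamma-responsive GTPases and antigen-processing genes were higher in both (T-like 0.66, percentile 100, NK-like 0.80, percentile 100). Socs1 (log2 2.26, 2.06 to 2.47) and Iigp1 (log2 1.66, 1.41 to 1.92) were T-like examples. Type I interferon-stimulated genes were higher too (0.67, percentile 100, and 0.69, percentile 99.96), led in T-like cells by Ly6a (log2 2.31, 2.19 to 2.44).

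Wild-type B-like cells had few genes past 2-fold. The feedback inhibitor of cytokine signalling Socs3 (6.44 and 156 CPM, log2 4.60, 4.21 to 5.01) and the transcriptional inhibitor Id2 (11.2 and 116 CPM, log2 3.37, 3.07 to 3.68) had the highest ratios. Pmepa1 (11.6 and 93.4 CPM, log2 3.01, 2.71 to 3.32) and the glucocorticoid-induced co-chaperone Fkbp5 (24.9 and 147 CPM, log2 2.56, 2.36 to 2.77) came next. The lowest were those of Jchain (225 and 11.4 CPM, log2 -4.29, -4.55 to -4.05), the joining chain of secreted antibodies, and Hsph1 (58.2 and 11.6 CPM, log2 -2.33, -2.60 to -2.06). The complement regulator Cd55 (362 and 92.1 CPM, log2 -1.98, -2.07 to -1.88), a naming marker of follicular B cells, was also among the lowest. The ratio of Jchain turned to log2 1.92 with clustering on the response genes. The NF-kB list stood near the class median (2 of 15 at least 2-fold higher, 1 lower, median 0.05, percentile 74.5), although Plaur (log2 1.54, 1.38 to 1.70) and Bcl3 (log2 1.46, 1.26 to 1.65) were higher. Glucocorticoid-responsive genes were higher (5 of 8 at least 2-fold higher, 0 lower, median 1.22, percentile 100). Lymphocyte activation and egress genes were lower (2 of 17 at least 2-fold higher, 5 lower, median -0.49, percentile 0), among them Gpr183 (log2 -1.21, -1.33 to -1.08), but the median turned to 0.023 with the low filter of 20 UMIs.

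The other lists in wild-type were as follows. Glucocorticoid-responsive genes had relative medians of 0.48, percentile 99.8 in T-like, 0.75, percentile 99.8 in NK-like and 0.71, percentile 97.51 in neutrophil-like cells. The values were 0.78, percentile 99.3 in monocyte/macrophage-like and 1.10, percentile 99.95 in dendritic-like cells. Glycolysis, hypoxia and metal-response genes were higher in monocyte/macrophage-like cells (9 of 21 at least 2-fold higher, 1 lower, median 0.87, percentile 99.93). These were led by Fth1 (log2 3.09, 3.05 to 3.14), a ferritin chain, and Mt1 (log2 3.13, 2.81 to 3.46). Cell death genes stood at 0.07, percentile 67.6 in monocyte/macrophage-like and 0.59, percentile 99.3 in dendritic-like cells. The pro-apoptotic Bcl2l11 (log2 3.88, 3.27 to 4.56) was higher in dendritic-like and the inflammasome gene Nlrp3 (log2 3.02, 2.49 to 3.59) in monocyte/macrophage-like cells. Components of the TLR4 and TNF receptor pathways had 5 of 15 at least 2-fold higher, 3 lower, median 0.38, percentile 90.4 in neutrophil-like cells. They had 4 of 17 at least 2-fold higher, 2 lower, median 0.12, percentile 68.5 in monocyte/macrophage-like cells. Dissociation and heat-shock genes were lower in dendritic-like cells (0 of 16 at least 2-fold higher, 4 lower, median -0.29, percentile 0.28) and T-like cells (-0.20, percentile 2.27, turned to 0.042 with the low filter of 20 UMIs). Cell cycle genes had 2 of 7 at least 2-fold higher, 0 lower, median 1.29, percentile 99.3 in neutrophil-like cells. Haemoglobin and erythroid RNA had 5 of 5 at least 2-fold higher, 0 lower, median 3.24, percentile 99.95 in monocyte/macrophage-like cells. Sex-linked transcripts had too few measured members in every class for a median.

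The same comparison in the libraries labelled TRIF-KO asked how RNA levels differed with TNF where TRIF was labelled as absent. NF-kB genes and chemokines were higher in phagocytes, as in wild-type, and more genes lay within 2-fold in all 6 classes. Counts of genes at least 2-fold higher and lower were 400 and 465 in monocyte/macrophage-like, 258 and 724 in neutrophil-like and 140 and 262 in dendritic-like cells. They were 87 and 137 in NK-like, 57 and 23 in T-like and 38 and 12 in B-like cells. Counting noise alone gave 52.2 and 7 in neutrophil-like cells and at most 4.4 and 4.25 in another class. Median-of-ratios scaling gave 425 and 344 in neutrophil-like and 109 and 113 in NK-like cells. CPM without the abundant gene families gave 111 and 103 in NK-like cells.

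In monocyte/macrophage-like cells of the libraries labelled TRIF-KO, Saa3 (33.1 and 5662 CPM, log2 7.42, 6.98 to 7.89) and Mmp14 (1 and 854 UMIs, log2 9.18, 6.70 to 14.48) had the highest ratios. AA467197 (3.16 and 348 CPM, log2 6.79, 5.42 to 8.67) and the scavenger receptor Marco (18.1 and 1125 CPM, log2 5.95, 5.37 to 6.62), a naming marker of marginal zone macrophages, followed. The lowest were those of Prg4 (165 and 2 UMIs, log2 -6.93, -9.98 to -5.05), Mtus1 (96 and 2 UMIs, log2 -6.15, -9.21 to -4.25) and the lipoxygenase Alox15 (at least 55.6-fold lower, 113 and 0 UMIs). 1 cell of the PBS library labelled TRIF-KO held all 113 UMIs of Alox15 and all 165 of Prg4 there. With each cell weighted equally the values of Saa3 and Mmp14 were log2 8.79 and 5.81, and without the cells holding Alox15 or Prg4 that of Saa3 was log2 11.16. In neutrophil-like cells the highest were Saa3 (1 and 3531 UMIs, log2 8.49, 6.01 to 13.79), the lipase Lipg (1 and 1489 UMIs, log2 7.24, 4.76 to 12.55) and Traf1 (at least 21.5-fold higher, 0 and 634 UMIs). Thrombospondin 1, Thbs1 (log2 5.99, 4.64 to 7.87), was higher as well, with log2 1.97 where doublets were kept. The lowest there were Ccl6 (2206 and 88.1 CPM, log2 -4.65, -4.86 to -4.44), Fgl2 (1443 and 56.5 CPM, log2 -4.68, -4.94 to -4.42) and Tspan13 (264 and 12.1 CPM, log2 -4.45, -5.06 to -3.86). In dendritic-like cells the highest were Fabp5 (145 and 3579.8 CPM, log2 4.63, 4.39 to 4.87), Ifitm1 (log2 5.76, 5.12 to 6.50), AA467197 (1 and 103 UMIs, log2 6.17, 3.66 to 11.49) and Mt1 (log2 4.06, 3.51 to 4.66). The lowest there were Anxa1 (85 and 2 UMIs, log2 -5.93, -9.00 to -4.03), Mmp12 (41 and 1 UMIs, log2 -5.87, -11.21 to -3.32) and Cd209a (log2 -3.79, -4.45 to -3.20), a naming marker. T-like cells had Gzmb (log2 4.36, 3.74 to 5.06), Gadd45g (log2 3.85, 3.15 to 4.65), Ly6a (log2 2.67, 2.57 to 2.77) and Socs3 (log2 2.47, 2.31 to 2.64) higher, with 15 of the 21 PBS UMIs of Gzmb in 1 cell (log2 6.01 without the top cell). Art2b (log2 -1.45, -1.67 to -1.24), Tent5a (log2 -1.38, -1.55 to -1.22) and Crip1 (log2 -1.35, -1.41 to -1.28) were lower. NK-like cells had Serpina3f (at least 45.6-fold higher, 0 and 139 UMIs), Cxcl10 (at least 11.2-fold higher, 0 and 34 UMIs, log2 2.01 without the top cell), Il7r (log2 3.56, 2.11 to 5.50) (log2 1.75 with doublets kept) and Serpina3g (log2 3.23, 2.84 to 3.64) higher. The maturation genes S1pr5 (log2 -2.25, -2.97 to -1.59) and Tbx21 (log2 -2.15, -2.86 to -1.5) were lower, as was Ly6c2 (log2 -2.13, -2.5 to -1.78). B-like cells had Socs3 (log2 3.72, 3.35 to 4.11), Fkbp5 (log2 3.23, 3.01 to 3.45), the phosphatase Ptpn22 (log2 2.64, 2.52 to 2.76) and Pmepa1 (log2 2.58, 2.29 to 2.88) higher. Il4i1 (log2 -1.70, -1.84 to -1.57), Fcer2a (log2 -1.38, -1.44 to -1.31) and Cd55 (log2 -1.30, -1.37 to -1.23) were lower.

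By list, NF-kB genes in the libraries labelled TRIF-KO had 18 of 30 at least 2-fold higher, 0 lower, median 1.30, percentile 100 in monocyte/macrophage-like and 17 of 28 at least 2-fold higher, 1 lower, median 1.86, percentile 100 in neutrophil-like cells. In dendritic-like cells the list had 6 of 25 at least 2-fold higher, 1 lower, median 0.68, percentile 100. Its relative medians were 0.81, percentile 100 in T-like, 1.10, percentile 100 in NK-like and -0.03, percentile 30.7 in B-like cells. Inflammatory effectors stood at 3.45, percentile 100 in monocyte/macrophage-like and 1.98, percentile 100 in neutrophil-like cells. Chemokines stood at 3.01, percentile 100 and 1.74, percentile 99.91 in the same classes. Type I interferon-stimulated genes stood at 0.31, percentile 91.6 in neutrophil-like, 0.55, percentile 100 in T-like and 0.32, percentile 100 in B-like cells. The interferon-gamma list stood at 0.45, percentile 100 in T-like and 0.58, percentile 99.99 in NK-like cells.

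The difference between the TNF responses, the response in the libraries labelled TRIF-KO minus that in wild-type, addresses the stated aim of the series. A value above 0 is a higher ratio of TNF to PBS in the libraries labelled TRIF-KO, which can come from a gene that was less strongly lower with TNF. NF-kB target genes had a smaller response in the libraries labelled TRIF-KO in 5 of the 6 classes. The relative medians were -0.97 (-0.98 at the floor), percentile 0 in dendritic-like and -0.75 (-0.76 at the floor), percentile 0 in monocyte/macrophage-like cells. They were -0.59 (-0.79 at the floor), percentile 0 in neutrophil-like, -0.46, percentile 0 in T-like and -0.45, percentile 0.34 in NK-like cells, against -0.06, percentile 20.5 in B-like cells. By at least 2-fold, 8 of 30 members were lower and 0 higher in monocyte/macrophage-like cells, 11 of 28 and 0 in neutrophil-like cells, and 10 of 25 and 0 in dendritic-like cells. The counts were 2 of 15 lower and 1 higher in NK-like, 0 of 17 and 0 in T-like and 1 of 15 and 0 in B-like cells. Chemokine responses were smaller in neutrophil-like (-2.09 (-2.12 at the floor), percentile 0) and dendritic-like cells (-2.19 (-2.27 at the floor), percentile 0). They stood at -0.23, percentile 19.2 in monocyte/macrophage-like cells. The inflammatory effectors as a group did not stand apart in neutrophil-like (0.07 (0.06 at the floor), percentile 57.9) or monocyte/macrophage-like cells (-0.15 (-0.16 at the floor), percentile 21.5).

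**Figure D2:**
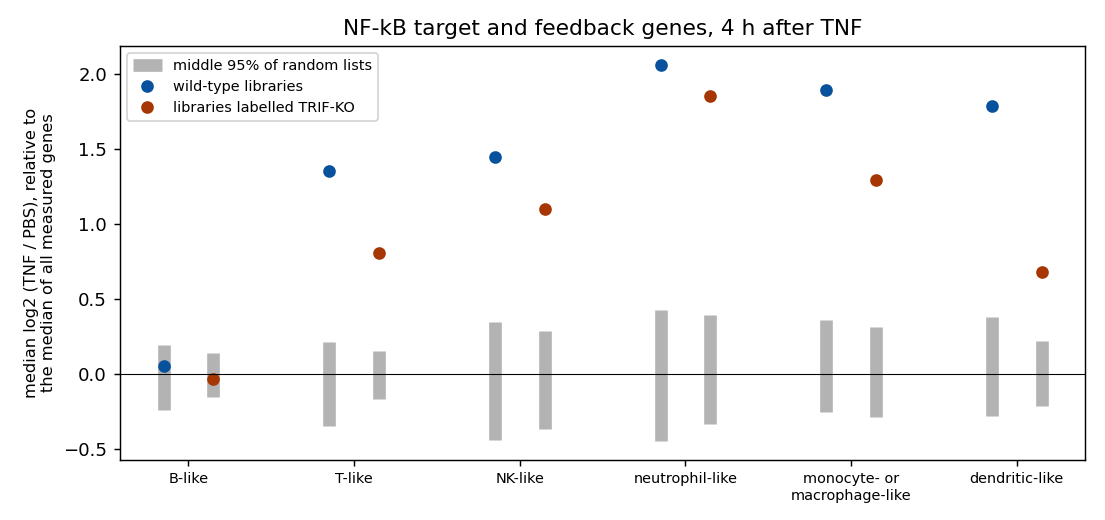
Median log2 ratio of TNF to PBS of the NF-kB target and feedback genes in 6 cell classes, relative to the median of all measured genes, for the wild-type libraries and those labelled TRIF-KO, with grey bars for the middle 95% of 10000 random lists of matched expression. The medians run from 0.05 in B-like to 2.06 in neutrophil-like cells in wild-type and from -0.03 to 1.86 in the libraries labelled TRIF-KO.

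Among single genes of monocyte/macrophage-like cells, the smaller responses included interleukin 1 beta (Il1b (log2 -1.67, -2.10 to -1.24), 171, 958, 63.1 and 112 CPM), Cd14 (log2 -1.38, -1.92 to -0.84) and Traf1 (log2 -2.06, -3.0 to -1.12). Others were the NF-kB inhibitor Tnfaip3 (log2 -1.73, -2.58 to -0.87), Nlrp3 (log2 -1.74, -2.47 to -1.02) and the co-stimulatory gene Cd83 (log2 -2.82, -3.71 to -1.94). The erythroid enzyme gene Bpgm (log2 -3.09, -4.14 to -2.04) also had a value below 0. Haemoglobin and erythroid RNA had 0 of 5 at least 2-fold higher, 5 lower, median -3.24 (-3.26 at the floor), percentile 0, with more of it in the PBS library labelled TRIF-KO. This list was not screened for free RNA. The response of Saa3 (log2 2.5, 1.97 to 3.03), at 70.5, 2115, 33.1 and 5662 CPM, was larger. Values above 0 were also those of 3 genes that were lower with TNF in wild-type, Chil3 (log2 2.97, 2.68 to 3.27), a naming marker at 1448, 160.3, 764 and 668 CPM, Mmp19 (log2 3.59, 2.61 to 4.58) and the nuclear lamin Lmna (log2 5.08, 3.12 to 7.04), with 86, 2, 20 and 50 UMIs. Cxcl10 (log2 2.36, 1.44 to 3.27) was above 0 too, at 157, 235, 8.68 and 69.5 CPM, with its lowest level in the PBS library labelled TRIF-KO. With each cell weighted equally the differences of Cd14, Il1b, Nlrp3 and Cxcl10 were -0.36, -0.84, -0.92 and 0.63, those of Tnfaip3 and Saa3 -2.87 and 4.29, and that of Bpgm turned to 0.48. Without the top cell the difference of Il1b was -1.10 and that of Cxcl10 turned to -0.54. Of Cxcl10, 1 cell held 196 of 200 UMIs in the wild-type PBS library and 1 cell 147 of 176 in the wild-type TNF library. With doublets kept the difference of Lmna was 2.89, and without cells holding Alox15 or Prg4 that of Saa3 was 6.03 and that of Il1b -0.86.

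In neutrophil-like cells the responses of Bcl2a1b (log2 -3.96, -6.20 to -1.72), Sod2 (log2 -2.55, -3.62 to -1.48), the chemerin-binding receptor Ccrl2 (log2 -3.81, -4.94 to -2.67) and Irak3 (log2 -1.67, -2.58 to -0.75) were smaller. Values below 0 were also those of Ffar2 (log2 -4.75, -6.42 to -3.08), a receptor for short-chain fatty acids that was higher with TNF in wild-type and lower in the libraries labelled TRIF-KO, and Il1b (log2 -1.23, -1.35 to -1.10), at 3439, 3163, 4409.5 and 1735 CPM. The metalloreductase Steap4 (log2 4.09, 2.87 to 5.30), at 292, 12.9, 135 and 111 CPM (log2 5.41 without the top cell), and the interferon-induced Oas2 (log2 3.87, 2.24 to 5.49) and Rsad2 (log2 2.39, 1.41 to 3.37) had values above 0 and were lower with TNF in wild-type. The naming marker Mmp8 (log2 2.48, 2.24 to 2.72) was above 0 as well. So were type I interferon-stimulated genes as a group (11 of 27 at least 2-fold higher, 0 lower, median 0.62 (0.65 at the floor), percentile 99.96), which were lower with TNF in wild-type and lower with PBS in the library labelled TRIF-KO. In dendritic-like cells the responses of Fscn1 (log2 -5.21, -6.34 to -4.07), Ccr7 (log2 -3.08, -3.60 to -2.56) and Gadd45b (log2 -2.57, -3.13 to -2.02) were smaller. Values of Hmox1 (log2 -5.54, -7.42 to -3.66), the haem-degrading enzyme, the chemokine Ccl5 (log2 -4.23, -4.52 to -3.95) and Cd80 (log2 -2.24, -3.12 to -1.35) were below 0, with ratios above 1 in wild-type and below 1 in the libraries labelled TRIF-KO. Of Hmox1, 1 cell held 42 of 59 UMIs in the wild-type TNF library and 1 cell 51 of 87 in the PBS library labelled TRIF-KO, and without the top cell its difference was -3.89. The granule gene Ngp (log2 8.66, 6.07 to 11.25), with 846, 3, 2 and 6 UMIs, was above 0 mainly through 1 cell of the wild-type PBS library (log2 1.29 without the top cell). Lymphocyte activation and egress genes had values below 0 in dendritic-like (-0.82 (-0.83 at the floor), percentile 0) and monocyte/macrophage-like cells (-1.13 (-1.14 at the floor), percentile 0).

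In lymphocytes values below 0 were those of genes that were higher with TNF in wild-type, Frmd4b (log2 -3.25, -4.41 to -2.08), Cirbp (log2 -1.76, -2.04 to -1.48), Vps37b (log2 -1.60, -1.81 to -1.38), Junb (log2 -1.28, -1.42 to -1.14) and Socs1 (log2 -1.2, -1.46 to -0.94) in T-like cells. They were those of Bcl2l11 (log2 -1.97, -2.71 to -1.23), Rbm3 (log2 -1.90, -2.43 to -1.38) and Mxd1 (log2 -1.85, -2.58 to -1.11) in NK-like cells. In B-like cells they were those of Lrrc58 (log2 -1.64, -1.89 to -1.40), Cirbp (log2 -1.52, -1.69 to -1.34) and Rbm3 (log2 -1.39, -1.49 to -1.29). Values above 0 were those of genes that were lower with TNF in wild-type, Xcl1 (log2 2.59, 2.12 to 3.06), Id3 (log2 2.16, 1.70 to 2.61) and Hsph1 (log2 1.94, 1.5 to 2.38) in T-like cells. Thy1 (log2 2.55, 1.30 to 3.81), Ccl4 (log2 1.95, 1.27 to 2.64) and Utp3 (log2 1.74, 0.90 to 2.57) were such genes in NK-like cells. Without the top cell the differences of Xcl1 and Ccl4 were 2.18 and 1.30. In B-like cells they were Jchain (log2 5.23, 4.96 to 5.51), at 225, 11.4, 48.2 and 92.8 CPM (log2 1.14 with clustering on the response genes, and 1317 of 1918 UMIs of the wild-type PBS library in 1 cell), Hsph1 (log2 1.60, 1.26 to 1.93) and BE692007 (log2 1.13, 1.04 to 1.21).

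By at least 2-fold, the ratio of TNF to PBS was higher in the libraries labelled TRIF-KO for 305 and lower for 135 genes in monocyte/macrophage-like cells, where counting noise alone gave 31.2 and 26.4. The counts were 333 and 367 in neutrophil-like cells (89.1 and 63.8 from noise) and 262 and 158 in dendritic-like cells (26.5 and 23). They were 133 and 77 in NK-like cells (48.8 and 44.1), 23 and 26 in T-like and 12 and 12 in B-like cells. Median-of-ratios scaling gave 163 and 214, 185 and 195, 9 and 33 and 4 and 16 in monocyte/macrophage-like, dendritic-like, T-like and B-like cells. Across genes, which are not independent replicates, the 2 responses had Pearson correlations of 0.65 in NK-like to 0.86 in monocyte/macrophage-like cells.

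With PBS alone, the genotype comparison gave the baseline on which the responses rest. B-like and T-like cells differed at few genes (3 higher and 6 lower in the library labelled TRIF-KO, and 3 and 2), and NK-like cells at 13 and 33. Myeloid cells differed at more, 86 and 90 in monocyte/macrophage-like, 160 and 228 in neutrophil-like and 124 and 77 in dendritic-like cells. Counting noise alone gave 24.4 and 36.8 in neutrophil-like, 5.65 and 5.05 in NK-like and at most 4.7 and 3.2 in another class. Median-of-ratios scaling gave 110 and 62 in monocyte/macrophage-like and 6 and 4 in B-like cells, and CPM without the abundant gene families 102 and 68 and 4 and 4. Rbm3 (log2 1.10, 1.01 to 1.19) was higher in B-like cells, with log2 1.02, 0.90 to 1.14 in T-like and log2 1.48, 0.99 to 1.99 in NK-like cells. Lower in the library labelled TRIF-KO were Jchain (log2 -2.22, -2.35 to -2.09), which turned to log2 1.48 with clustering on the response genes, and the histone genes Hist1h4d (log2 -1.22, -1.39 to -1.04) and Hist1h1e (log2 -1.2, -1.33 to -1.08) in B-like cells. In T-like cells Xcl1 (log2 -1.58, -1.89 to -1.28) was lower, and Hist1h4d stood at log2 -1.16, -1.39 to -0.93. Ccl4 (log2 -1.61, -1.94 to -1.29), Xcl1 (log2 -1.28, -1.61 to -0.95) and Pim2 (log2 -2.17, -3.75 to -0.83) were lower in NK-like cells, where Cxcr4 (log2 1.45, 0.39 to 2.64), Ndufs4 (log2 1.25, 0.63 to 1.92) and Imp3 (log2 1.02, 0.38 to 1.70) were higher. In the wild-type PBS library 1 T-like cell held 97 of 247 UMIs of Xcl1, and 1 NK-like cell held 84 of 240 of Xcl1 and 1 held 105 of 284 of Ccl4. Without the top cell Xcl1 stood at log2 -1.35 in T-like and -0.89 in NK-like cells and Ccl4 at log2 -1.05.

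In neutrophil-like cells of the PBS library labelled TRIF-KO, Camp (2461 and 8244 CPM, log2 1.74, 1.66 to 1.83) and the granulocyte transcription factor Cebpe (log2 2.52, 1.79 to 3.28) were higher, as were the mitotic gene Ube2c (log2 3.43, 2.35 to 4.67) and Rap1gap2 (log2 2.78, 1.73 to 3.93). Mmp8 (2995 and 558 CPM, log2 -2.42, -2.66 to -2.20), a naming marker, Hist1h2ae (log2 -5.52, -10.84 to -3.02) and Cstdc5 (at least 7.42-fold lower, 60 and 0 UMIs) were lower. 1 cell held 35 of the 36 UMIs of Ube2c and 1 cell 111 of the 124 of Hist1h2ae in the library with the higher level, and without the top cell their values were log2 -0.84, a turned direction, and -0.63. Camp was read in 6 cells of each PBS library (log2 2.25 without the top cell), and 1 cell held 27 of the 51 UMIs of Cebpe (log2 1.98 without the top cell). Type I interferon-stimulated genes (-0.71, percentile 0) and inflammatory effectors (-0.55, percentile 0.12) were lower as groups in neutrophil-like cells. In monocyte/macrophage-like cells, Alox15 (at least 37.9-fold higher, 0 and 113 UMIs), Prg4 (at least 55.4-fold higher, 0 and 165 UMIs), Itga6 (2 and 99 UMIs, log2 5.64, 3.75 to 8.71) and Bpgm (log2 3.45, 2.55 to 4.49) were higher. All UMIs of Alox15 and Prg4 and 93 of those of Itga6 (log2 2.64 without the top cell) lay in 1 cell. The chemokine Cxcl10 (157 and 8.68 CPM, log2 -4.17, -5.20 to -3.30) and Mmp19 (log2 -2.79, -3.61 to -2.04) were lower, but Cxcl10 turned to log2 1.004 without the top cell. Inflammatory effectors were lower there (1 of 14 at least 2-fold higher, 8 lower, median -1.05, percentile 0), as was Saa3 (log2 -1.09, -1.65 to -0.55). Haemoglobin and erythroid RNA was higher (5 of 5 at least 2-fold higher, 0 lower, median 2.88, percentile 100). Without cells holding Alox15 or Prg4 the value of Saa3 was log2 -4.83. With each cell weighted equally Alox15, Prg4, Bpgm, Cxcl10 and Saa3 stood at log2 1.90, 2.45, 1.07, -2.33 and -3.33, and Ube2c in neutrophil-like cells at log2 1.04. In dendritic-like cells Socs2 (1 and 68 UMIs, log2 6.09, 3.56 to 11.41), Hmox1 (2 and 87 UMIs, log2 5.44, 3.55 to 8.51), Fscn1 (6 and 192 UMIs, log2 5.0, 3.85 to 6.46) and Vcam1 (2 and 64 UMIs, log2 5.0, 3.09 to 8.08) were higher, with 51 of the UMIs of Hmox1 and 35 of Vcam1 in 1 cell each. Ngp (846 and 2 UMIs, log2 -8.72, -11.77 to -6.87), Camp (at least 126-fold lower, 377 and 0 UMIs) and Ltf (at least 105-fold lower, 316 and 0 UMIs) were lower, through the 1 cell named above. NF-kB genes were higher at baseline in dendritic-like cells (0.34, percentile 99.98) and not in monocyte/macrophage-like (0.10, percentile 87.6) or neutrophil-like cells (-0.30, percentile 2.47).

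After TNF, the genotype comparison gave the levels reached under each genotype label. Interleukin 1 beta, Il1b (958 and 112 CPM, log2 -3.10, -3.33 to -2.87), and the chemoattractant Cxcl2 (632 and 83.4 CPM, log2 -2.92, -3.19 to -2.66) were lower in monocyte/macrophage-like cells of the library labelled TRIF-KO. Acod1 (log2 -2.16, -2.60 to -1.74), Ifi205 (log2 -2.05, -2.23 to -1.87), Traf1 (log2 -1.68, -1.96 to -1.41) and Nlrp3 (log2 -1.54, -1.88 to -1.21) were lower too. Saa3 (2115 and 5662 CPM, log2 1.42, 1.34 to 1.5) and Chil3 (160.3 and 668 CPM, log2 2.06, 1.79 to 2.34) were higher. So were Rgs3 (log2 2.46, 1.62 to 3.44) and Lmna (2 and 50 UMIs, log2 3.32, 1.39 to 6.41) (log2 0.83 with doublets kept). The NF-kB list was lower after TNF in 5 of the 6 classes. It stood at -0.72, percentile 0 in monocyte/macrophage-like, -0.70, percentile 0 in neutrophil-like and -0.62, percentile 0 in dendritic-like cells (-0.37 with the stricter filter). Its values were -0.61, percentile 0 in T-like and -0.84, percentile 0 in NK-like cells, against -0.07, percentile 5.04 in B-like cells. Chemokines were lower in neutrophil-like (-1.92, percentile 0), monocyte/macrophage-like (-1.45, percentile 0) and dendritic-like cells (-1.04, percentile 0).

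In neutrophil-like cells after TNF, the chemokine Cxcl3 (238 and 8.07 CPM, log2 -4.88, -5.58 to -4.24), Tnfaip3 (log2 -2.04, -2.32 to -1.75), Icam1 (log2 -1.62, -1.88 to -1.36), Bcl2a1b (log2 -1.68, -1.89 to -1.46) and Acod1 (log2 -1.30, -1.46 to -1.13) were lower in the library labelled TRIF-KO. Steap4 (log2 3.11, 1.97 to 4.57), Trp53inp1 (log2 2.98, 1.99 to 4.20), Rgs3 (log2 2.46, 1.60 to 3.47) and Igfbp6 (at least 4.29-fold higher, 0 and 82 UMIs) were higher. The B-cell genes Ebf1 (log2 -3.55, -4.24 to -2.88) and Cd79a (log2 -3.08, -3.60 to -2.57) were lower too, their RNA being present in the neutrophil-like cells of the wild-type TNF library (log2 -0.56 and -0.71 with doublets kept). In dendritic-like cells Ccl17 (log2 -3.43, -4.32 to -2.64), Mt2 (log2 -2.08, -2.67 to -1.51) and Ifitm6 (log2 -1.92, -2.30 to -1.54) were lower. Smim5 (log2 2.70, 1.72 to 3.88), Cd180 (log2 2.37, 1.30 to 3.64), Ebf1 (log2 2.29, 1.51 to 3.18) and the plasmacytoid marker Klk1 (log2 1.94, 1.47 to 2.43) were higher, with log2 0.66 for Ebf1 and 0.97 for Klk1 where doublets were kept. T-like cells had Frmd4b (log2 -1.87, -2.12 to -1.62), the kinase Map3k8 (log2 -1.82, -2.02 to -1.62) and Neurl3 (log2 -1.44, -1.60 to -1.27) lower. Id3 (log2 2.30, 1.88 to 2.74), Dtx1 (log2 1.41, 1.17 to 1.66), the pro-apoptotic Bbc3 (log2 1.31, 1.09 to 1.53) and Dynll1 (log2 1.11, 0.98 to 1.24) were higher. NK-like cells had Cxcl10 (log2 -2.39, -2.98 to -1.83), Gpr18 (log2 -2.26, -2.99 to -1.58) and Kdm2b (log2 -2.23, -3.11 to -1.42) lower. Arl4d (log2 2.01, 0.75 to 3.54), Cdc42ep3 (log2 1.61, 0.69 to 2.64), Tmem71 (log2 1.58, 0.66 to 2.62) and Klra9 (log2 1.29, 0.85 to 1.74) were higher. In B-like cells Id2 (log2 -1.37, -1.49 to -1.25), Socs3 (log2 -1.29, -1.40 to -1.19) and Plaur (log2 -1.11, -1.22 to -1.0) were lower.

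Counts of genes at least 2-fold higher and lower in the TNF library labelled TRIF-KO were 183 and 79 in monocyte/macrophage-like (123 and 103 with median-of-ratios scaling), 160 and 177 in neutrophil-like (195 and 139) and 133 and 44 in dendritic-like cells (101 and 55). They were 56 and 44 in NK-like, 6 and 29 in T-like and 2 and 4 in B-like cells (0 and 4 with CPM without the abundant gene families). Counting noise alone gave 14.6 and 6, 25.85 and 3.25, 6.65 and 3.85, 17.85 and 10.55, 0 and 0, and 0 and 0 in the same order of classes. As a group, glucocorticoid-responsive genes were lower in monocyte/macrophage-like cells (-0.42, percentile 0.02). Components of the TLR4 and TNF receptor pathways stood at -0.36, percentile 1.88 in neutrophil-like cells.

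**Figure D3:**
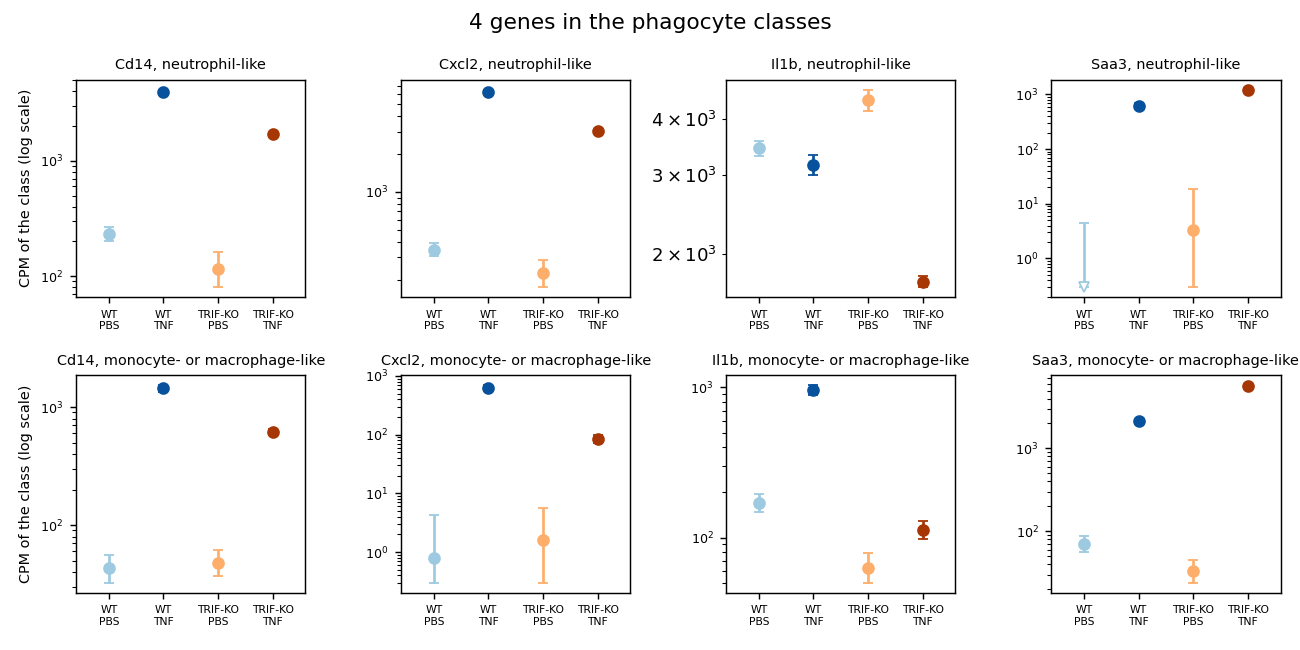
Levels of Cd14, Cxcl2, Il1b and Saa3 in CPM (vertical log axes, a scale per panel) in neutrophil-like and monocyte/macrophage-like cells of the 4 libraries, with exact 95% Poisson intervals as bars, lower ends below 0.3 CPM drawn at 0.3, and a count of 0 drawn as an open triangle at 0.3. After TNF, Cd14, Cxcl2 and Il1b were lower and Saa3 higher in the library labelled TRIF-KO in both classes, for example 112 against 958 CPM of Il1b in monocyte/macrophage-like cells.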

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

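The test of the neutrophil share without erythroid-like cells was chosen after its result had been seen, and that with failed barcodes was fixed before.

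Neutrophil-like cells were a smaller share with TNF in wild-type (ratio 0.244) and a larger one in the libraries labelled TRIF-KO (ratio 2.88), and this difference in direction was not tested, since each group held 1 library. With every failed barcode added to its most similar class, the log2 ratios were -2.20 in wild-type and 1.58 in the libraries labelled TRIF-KO. This argues against loss to the filters used here. The assignment, unchecked on failed barcodes, returned 96.4% of kept cells to their own class. Without erythroid-like, platelet-like and unnamed cells the log2 ratio in the libraries labelled TRIF-KO was 1.69, which argues against erythroid-like cells in the denominator. Loss at red-cell lysis, dead-cell removal or barcode selection before deposit, a difference between mice and the genotype stay open and untested. The PBS libraries also differed (6.78% and 1.85%), so the opposite directions rest on both arms.

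The share of B-like cells had ratios of TNF to PBS of 1.10 in wild-type and 0.840 in the libraries labelled TRIF-KO, opposite directions whose difference was not tested. The same held for T-like cells (1.17 and 0.851) and, the other way round, for monocyte/macrophage-like cells (0.639 and 1.2), likewise not tested. Neutrophil granule and surface proteins in dendritic-like cells had relative median log2 ratios of -5.07 in wild-type and 0.78 in the libraries labelled TRIF-KO, not tested, and the former rests mainly on 1 cell of the wild-type PBS library, being -0.26 without cells holding Ngp, Camp and Ltf, while the latter turned to -0.14 with the stricter filter.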

How the results depend on the processing

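No paired analysis was possible because each group held 1 library and the labels share no replicate numbers. Choices made after the data were seen, and not planned, were the use of relative medians, the thresholds of the naming score, the separate values of monocyte-like and macrophage-like cells and the 4 alternatives that left out cells. Depth limits the macrophage-like values most, with 97764 UMIs in 1 library, followed by neutrophil-like (302752), NK-like (333960), monocyte-like (568923), monocyte/macrophage-like (748478) and dendritic-like values (934877). The 1 library per group limits every comparison. Ticam1 kept its 4 values within their intervals with all barcodes. For the NF-kB list in the 5 classes other than B-like cells, the relative medians of both responses, of their difference and between the TNF libraries changed sign under none of the alternatives run, and its difference between the responses ran from -1.01 to -0.91 in dendritic-like, -0.86 to -0.70 in monocyte/macrophage-like, -0.87 to -0.43 in neutrophil-like, -0.50 to -0.35 in NK-like, -0.48 to -0.40 in T-like and -0.13 to -0.01 in B-like cells. Between the TNF libraries it ran from -0.63 to -0.37 in dendritic-like, -0.79 to -0.67 in monocyte/macrophage-like, -0.87 to -0.60 in neutrophil-like, -0.88 to -0.68 in NK-like and -0.67 to -0.48 in T-like cells. Causes of the movements below were not tested except where the construction shows it.

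With a low filter of 20 UMIs, which admits many genes of few counts and so more ratios past 2-fold by counting noise, all counts of genes moved. Higher and lower counts are given in the order B-like, T-like, NK-like, neutrophil-like, monocyte/macrophage-like and dendritic-like. The wild-type response gave 428 and 882, 575 and 1028, 554 and 1277, 928 and 1781, 898 and 2468, 677 and 2210. The response in the libraries labelled TRIF-KO gave 370 and 340, 422 and 322, 443 and 776, 595 and 1897, 881 and 1480, 491 and 1163. The difference between the responses gave 743 and 433, 908 and 458, 987 and 693, 1012 and 1555, 1508 and 724, 1535 and 771. The genotype comparison with PBS gave 218 and 554, 283 and 474, 373 and 402, 926 and 730, 544 and 425, 661 and 598. The genotype comparison with TNF gave 177 and 281, 333 and 286, 693 and 433, 625 and 807, 1152 and 362, 910 and 340.

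Thinning every library to the smallest class total, which leaves fewer UMIs per gene, gave in neutrophil-like cells 162 higher and 417 lower in wild-type, 144 and 361 in the libraries labelled TRIF-KO, 160 and 142 for the difference, 54 and 106 between genotypes with PBS and 84 and 94 with TNF. It gave 37 genes higher in NK-like cells between genotypes with TNF and 42 higher differences in T-like cells. Median-of-ratios scaling gave 39 genes lower in B-like, 188 in NK-like and 484 in neutrophil-like cells in wild-type, 425 higher and 344 lower in neutrophil-like cells labelled TRIF-KO, 6 higher in B-like cells between genotypes with PBS, and differences of 163 higher and 214 lower in monocyte/macrophage-like, 9 higher in T-like and 4 higher in B-like cells. CPM without the abundant gene families gave differences of 10 higher in T-like and 7 higher in B-like cells and 0 genes higher in B-like cells between genotypes with TNF.

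The mean over cells gave, in monocyte/macrophage-like cells, differences of 482 higher and 266 lower, 153 lower between genotypes with PBS, and 293 higher and 182 lower with TNF. In dendritic-like cells it gave 476 lower with TNF in the libraries labelled TRIF-KO and, between genotypes, 124 lower with PBS and 92 lower with TNF, and in T-like cells 5 lower with PBS. Leiden resolution 2 gave 479 higher differences and 157 lower genes between genotypes with PBS in monocyte/macrophage-like cells, 1 gene higher in B-like cells with TNF and 4 lower in T-like cells with PBS. The same T-like count was 4 with clustering on the response genes and 4 with doublets kept, and 8 with free-RNA genes kept. Between genotypes with TNF, B-like cells had 0 genes higher with clustering on the response genes, 0 with doublets kept, 0 with the stricter filter and 5 with free-RNA genes kept, which also gave 5 higher with PBS, and dendritic-like cells had 88 higher with doublets kept. The stricter filter gave in B-like cells 29 higher differences and, between genotypes, 10 lower with PBS and 8 lower with TNF, and in T-like cells 36 higher differences and 5 higher with PBS.

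Log2 ratios of shares moved with the stricter filter to -0.64 for B-like and -0.11 for T-like cells in the libraries labelled TRIF-KO and to 0.41 for T-like and -1.05 for monocyte/macrophage-like cells in wild-type, and without erythroid-like, platelet-like and unnamed cells to -0.090 for B-like and -0.070 for T-like cells in the libraries labelled TRIF-KO. The log2 ratio of the neutrophil share ran from -2.09 to -1.91 in wild-type and from 1.5 to 1.69 in the libraries labelled TRIF-KO over the alternatives run. Turns within their limits aside, 10 relative medians of lists changed sign. With the low filter these were dissociation and heat-shock genes in wild-type T-like cells (0.042), glucocorticoid genes in T-like cells between genotypes with TNF (-0.086), inflammatory effectors in dendritic-like cells labelled TRIF-KO (-0.011), lymphocyte activation genes in wild-type B-like cells (0.023), and granule genes in NK-like cells labelled TRIF-KO (0.38) and between genotypes with PBS (-0.036). With the stricter filter they were dissociation genes in B-like cells for the difference (-0.015) and granule genes in dendritic-like cells labelled TRIF-KO (-0.14), with the mean over cells glucocorticoid genes in monocyte/macrophage-like cells labelled TRIF-KO (-0.26), and with doublets kept granule genes in monocyte/macrophage-like cells between genotypes with TNF (0.033). Of 344 medians, 338 stayed within their limits with Leiden resolution 2, 340 with clustering on the response genes and 297 with the low filter. A scale per library or free-RNA genes kept cannot move a relative median.

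Among named genes, Jchain in B-like cells turned to 1.92 in wild-type and 1.48 between genotypes with PBS with clustering on the response genes, and the difference of Bpgm in monocyte/macrophage-like cells turned to 0.48 with the mean over cells, all on the log2 scale. Without the top cell, Cxcl10 in monocyte/macrophage-like cells turned to -0.54 for the difference and 1.004 between genotypes with PBS, Ngp in dendritic-like cells to 0.067 in wild-type and Ube2c in neutrophil-like cells to -0.84 between genotypes with PBS, since 1 cell held most UMIs of each. Fscn1 in wild-type dendritic-like cells stood at 8.06, Steap4 in neutrophil-like cells at 4.61 between genotypes with TNF, and Jchain in wild-type B-like cells at -2.67. With the mean over cells Jchain stood at -2.09 in wild-type and 3.73 for the difference, and Cxcl2 in monocyte/macrophage-like cells at -4.07 between genotypes with TNF. With the stricter filter Cxcl10 in NK-like cells stood at 2.13 in the libraries labelled TRIF-KO and -3.73 between genotypes with TNF, and Marco in monocyte/macrophage-like cells labelled TRIF-KO at 7.67. The difference of Irak3 in neutrophil-like cells was -2.73 with UMIs thinned, and that of Bpgm -5.44 with Leiden resolution 2 and -1.81 with doublets kept. Without macrophage-like cluster 13, Marco in monocyte/macrophage-like cells labelled TRIF-KO stood at 6.67 and the difference of Cd83 at -3.88.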

Other observations

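Among the tests of this part, those of single clusters, of Rbm3 and Cirbp over classes and of heat-shock genes were chosen after the results had been seen, as were 2 other choices of genes for the test of 1 common factor. The separate monocyte-like and macrophage-like values and the genes named in the next paragraph were also chosen after their values were seen.

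After TNF, Cd14 was lower in the library labelled TRIF-KO in both monocyte-like and macrophage-like cells, and the 2 were not compared by a test. In monocyte-like cells it was read at 22.9, 1109, 36.9 and 386 CPM, with a smaller response in the libraries labelled TRIF-KO (log2 -2.20, -2.92 to -1.48), and in macrophage-like cells at 286, 2484, 105 and 1267 CPM, with log2 0.47, -0.35 to 1.29 for the same difference, an interval that includes 0. Il1b stood at 169, 1062, 69.0 and 141 CPM in monocyte-like and at 194, 629, 33.4 and 30.6 CPM in macrophage-like cells, with differences of log2 -1.63, -2.08 to -1.18 and log2 -1.84, -3.28 to -0.41. The former was -0.50 with each cell weighted equally, -0.97 without the top cell and -0.71 without cells holding Alox15 or Prg4. The NF-kB list was smaller in its response in both, with relative medians of -0.82 (-0.83 at the floor), percentile 0 in monocyte-like and -0.57 (-0.59 at the floor), percentile 0.21 in macrophage-like cells. Marco stood at 307, 3297, 109.8 and 4219 CPM in macrophage-like cells. In macrophage-like cells of cluster 17 alone, since cluster 13 was present with PBS only, the differences were log2 0.80 (-0.24 to 1.84) for Cd14 and log2 -1.32 (-3.43 to 0.80), an interval that includes 0, for Il1b, the relative median of the NF-kB list was -1.38, and Marco stood at 228, 3297, 113 and 4219 CPM.

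Neutrophil-like cells of the libraries labelled TRIF-KO had higher RNA of glycolysis, hypoxia and metal-response genes with TNF (7 of 19 at least 2-fold higher, 2 lower, median 0.67, percentile 99.2). Cell death genes went both ways (4 of 16 at least 2-fold higher, 3 lower, median 0.58, percentile 98.6), with higher RNA of the nucleic-acid sensor Zbp1 (2 and 189 UMIs, log2 3.27, 1.39 to 6.32) and the inflammatory caspase Casp4 (log2 1.19, 0.72 to 1.70). Their cell cycle genes had 0 of 7 at least 2-fold higher, 5 lower, median -0.66, percentile 5.25, and the difference between the responses had 0 of 7 at least 2-fold higher, 6 lower, median -2.04 (-2.06 at the floor), percentile 0, with Mki67 at 51.5, 101, 102 and 48.7 CPM. In monocyte/macrophage-like cells labelled TRIF-KO the glycolysis list was higher (9 of 21 at least 2-fold higher, 1 lower, median 0.75, percentile 99.97) as in wild-type. The interferon-gamma list there stood at 0.62, percentile 99.8 in wild-type and 0.25, percentile 92.7 with the TRIF-KO label.

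The smaller NF-kB response in the libraries labelled TRIF-KO may reflect the genotype, or a smaller response to the injection behind 1 library. In the test fixed beforehand, 3.97% of 453 genes at least 2-fold higher in wild-type monocyte-like cells had a larger response in the libraries labelled TRIF-KO, under the 5% that 1 common factor would allow, so that test came out for a common factor. That choice of genes favours smaller values in the other genotype, and a choice by the response in the libraries labelled TRIF-KO, which favours larger ones, gave 19.4% of 444 genes larger and 17.8% smaller. A choice by the mean of both gave 9.22% of 423 larger and 30.3% smaller in monocyte-like cells, 2.51% to 13.8% larger in the 5 classes with a smaller response of the list and 38.5% of 39 in B-like cells, on both sides of the bounds of 5% and 10%, so a common factor and the genotype cannot be told apart with 1 library per group. A change in the makeup of subtypes is argued against in T-like, monocyte/macrophage-like and dendritic-like cells, since the list was lower in 8 of 8 single clusters (100%) between the TNF libraries, and left open in NK-like and neutrophil-like cells, with 0 clusters besides that of the whole class, and depth is argued against, since the value in neutrophil-like cells stood at -0.85 with UMIs thinned to the smallest class total, while a lower delivered dose, a difference between mice and the genotype stay open.

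Rbm3 and Cirbp, RNA-binding proteins induced by mild cold, were higher with TNF in all 6 classes of wild-type, with log2 ratios of 1.37 to 2.96, which argues against a property of 1 cell class. In the libraries labelled TRIF-KO the ratios ran from -0.36 to 1.05, smaller beyond counting error in 12 of 12 pairs of class and gene, and Rbm3 was higher in the PBS library labelled TRIF-KO by log2 0.63 to 1.48. A candidate explanation is a lower body temperature after TNF or of the cells before lysis, for which heat-shock genes in wild-type would lie below the class median, and they did so in 6 of 6 classes (-0.11 to -0.56) and in 2 of 6 in the libraries labelled TRIF-KO. The wild-type medians rest on 4 to 8 genes and lay at percentiles of 1.58 in B-like, 0.33 in T-like, 15.4 in NK-like, 30.045 in neutrophil-like, 8.63 in monocyte/macrophage-like and 0.66 in dendritic-like cells, so the test leaves this explanation open. Body temperature and handling of the tube cannot be separated here, since each group was 1 library, and apart from body temperature no biological explanation was tested.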
